A study of Mus musculus with 4 samples.

How the data were processed

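Dorsal skin was collected 48 h after male mice of the B6 strain received PBS (mock) or Staphylococcus aureus, a Gram-positive bacterium that infects skin. The mice had eaten a standard diet (SD) or a diet with 60% fat (HFD). Each of the 4 combinations was 1 library of single-cell RNA sequencing of transcript 3' ends in droplets, and the number of mice behind a library is not given in the sources used here. The authors deposited a matrix of UMI counts for each library, with 31053 genes and 1 column per cell barcode; a UMI (unique molecular identifier) marks 1 captured transcript. The deposited counts were whole numbers that had not been normalised. Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3.0.0 were used with the mouse build GRCm38 (mm10), and which step each tool served is not given in the sources used here. Positions of genes are those of GRCm38.

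Barcodes were kept with at least 250 genes, at least 500 UMIs and at most 15% mitochondrial UMIs. The mitochondrial limit removed 694, 267, 494 and 167 barcodes from mock SD, mock HFD, infected SD and infected HFD. The other limits removed 276, 265, 216 and 255, of which 275, 261, 197 and 203 held mostly haemoglobin transcripts. Scrublet, run on each library, called 11 doublets (0.174% of the cells that passed), so the caller has not worked here and doublets remain. With these removed, 6307 of 8952 barcodes and 61991265 of 69260538 UMIs were kept. Counts were scaled to 10000 UMIs per cell, and the 4 libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 1, which gave 34 clusters. A cluster was named from 18 fixed sets of marker genes when at least 3 markers of a class were detected at 20% of their highest cluster level or more and the 10 leading genes did not point to another class. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.

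UMIs were summed over the cells of a class in a library and given as CPM, which is 1000 times the count per 1000 UMIs of that sum, with exact Poisson intervals. Ratios of 2 libraries have intervals from the conditional binomial, and shares of cells have exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only. The comparisons were infected over mock within each diet and HFD over SD within each treatment, for classes with at least 50 cells in both libraries; keratinocytes did not reach this. With 1 library per group no test was made. Genes were counted past a rule of size with at least 30 UMIs in the 2 sums, a higher CPM of at least 50, a ratio of at least 2 and an interval that excludes 1.5. Mitochondrial, ribosomal protein, haemoglobin, Gm and Rik genes and Xist were left out. Genes under 20% of their CPM in another class with at least 20 cells in the library where they were higher were also left out, since free RNA can supply them. Genes were ranked by the interval bound nearest 1, and the first 12 in each direction were open to naming for fibroblasts and the first 6 for other classes, beside members of the fixed lists and Camp. Against a sum of 0 a ratio is a lower bound with 3 counts as the floor. Where 1 cell gave most UMIs of a gene named from this ranking, this is stated. Most genes named only as list members were not checked for it.

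The 19 gene lists were antimicrobial, adipogenesis, TGF-beta response and matrix, chemokines and cytokines, interferon response, NF-kB and pattern recognition, complement, MHC class I presentation, hypoxia and glycolysis, matrix proteases and inhibitors, lipid handling and fatty acid oxidation, dissociation stress and immediate early, proliferation, metallothionein and acute phase, keratinocyte wound response, inflammatory macrophage, resident macrophage, neutrophil granule, and neutrophil activation. A list's value is the median log2 CPM ratio (pseudocount 0.5) of members with at least 10 UMIs. Its interval comes from 1000 Poisson resamples, and its percentile from 10000 random lists of the same size matched on expression in 20 bins. The diet by infection value is the difference of the infection log2 ratios, HFD minus SD. To compare shares of cells with a UMI of a gene, each cell was thinned to 1000 UMIs, which left out 79, 37, 128 and 168 cells.

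The classes, lists, rule and comparisons were fixed before the data were examined. Alternatives were no cell filter, other limits on genes and mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, each library clustered alone, centred or TMM scaling, the mean of each cell's CPM, other limits of the size rule and of the background filter, and thinning. On simulated counts with 200 genes altered by known folds, the rule recovered 56% of 50 genes at 2-fold, 100% at 3-fold, 98% at 4-fold and 100% at 8-fold for fibroblasts of infected SD over mock SD (2435 genes), with 0 unaltered genes past it. Of the intervals of unaltered genes, 87.9% held 1. The simulated counts varied by Poisson error only, so these figures do not cover variation between cells, animals or libraries. A list altered by 1 on the log2 scale was returned as 1.01. A simulated diet by infection difference of 2 had a median of 2.01 over 200 of 2722 genes, and 85% of its intervals held the true value.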

Results

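The 4 libraries profiled skin of mice on a standard diet (SD) or a high fat diet (HFD), 48 h after mock treatment with PBS or infection with Staphylococcus aureus. The question behind the series is whether obesity brought on by diet alters the antimicrobial response of fibroblasts in the skin that can become fat cells. These progenitors did not form a class of their own here. Cluster 3 carried 6 of 12 adipocyte progenitor markers beside 6 of 6 of reticular fibroblasts, so fibroblast values cover all fibroblasts, of which the progenitors are a part. The matrices held 2690 barcodes with 19899116 UMIs in mock SD, 1335 with 13488623 in mock HFD, 2703 with 21804208 in infected SD and 2224 with 14068591 in infected HFD. After filtering, 1718, 802, 1986 and 1801 cells remained in that order, with medians of 7383, 12421.5, 6051 and 3692 UMIs per cell. Infected HFD stood apart with medians of 868 genes and 0.399% mitochondrial UMIs per cell, against 2385.5, 3142.5 and 2064 genes and 4.06%, 3.96% and 4.27% in mock SD, mock HFD and infected SD. There were no replicates. Values in brackets are 95% limits of counting error, and animals or library preparations are not separable from diet and infection.

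Neutrophils, granulocytes that enter infected tissue early, made up 15.6% [13.99, 17.2] of kept cells in infected SD and 60.6% [58.3, 62.8] in infected HFD. The mock libraries held 10 and 4 of them, 0.582% in mock SD and 0.499% in mock HFD. Neutrophils of infected HFD had a median of 727 genes per cell. The low gene median of that library was not seen in its fibroblasts, at 4736 against 3149, 3997 and 3721 in mock SD, mock HFD and infected SD. All immune classes together were 27.5% and 27.4% of the mock libraries, 45.5% of infected SD and 83.2% of infected HFD. Among cells other than neutrophils, macrophages and monocytes were 11.1% in mock SD, 7.52% in mock HFD, 12.999% in infected SD and 35.5% [32.0, 39.1] in infected HFD. Fibroblasts, the collagen-producing cells of the dermis, were 40.0%, 47.2%, 30.8% and 25.8% of the same cells. Cells of the dermal papilla or sheath, which belong to hair follicles, were 12.002%, 11.7% and 14.1% in the first 3 libraries and 1.69% in infected HFD. T and NK cells were 7.44% in mock SD and 14.5%, 17.2% and 15.4% in the others. Mast cells were 3.34% and 1.504% in the mock libraries against 0.239% and 0.141% in the infected ones. Blood endothelial cells were 5.97% in mock SD, 1.88% in mock HFD, 2.56% in infected SD and 0.423% in infected HFD. Keratinocytes were 6.44% in infected SD and 1.52%, 2.01% and 1.69% in mock SD, mock HFD and infected HFD. Clusters left unnamed held 10.4% of these cells in infected HFD and between 1.93% and 3.22% elsewhere.

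**Figure D1:**
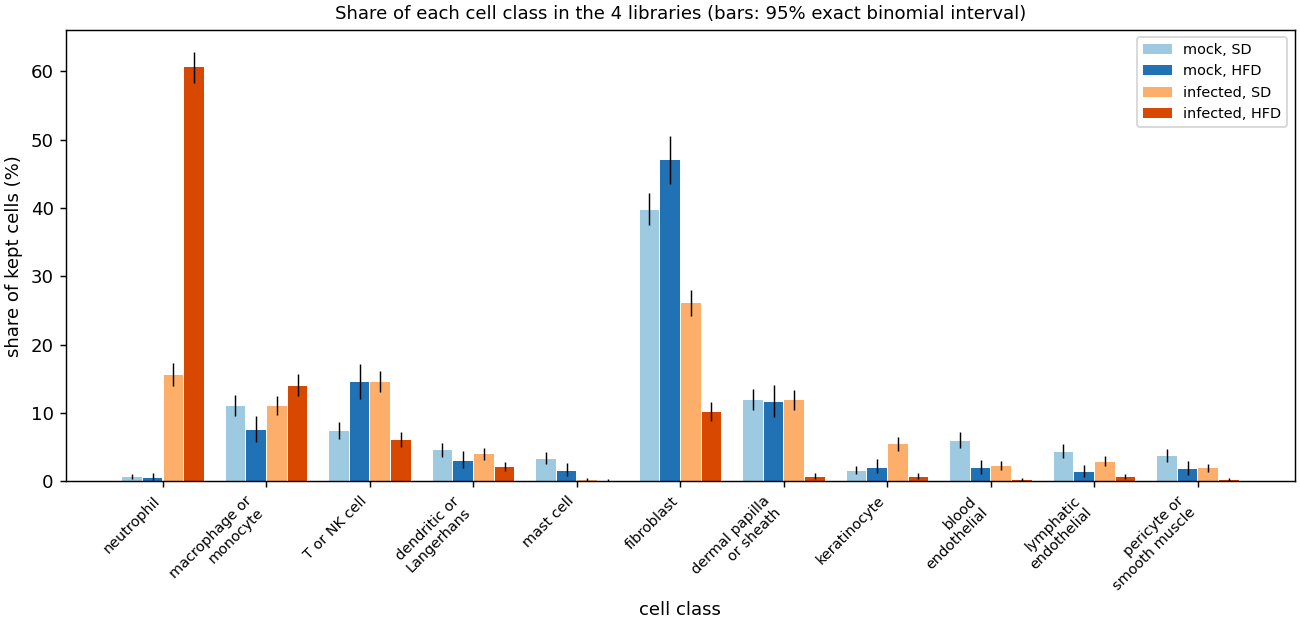
Share of kept cells in 11 classes for each library, with exact binomial 95% intervals. Neutrophils were 0.582%, 0.499%, 15.6% and 60.6% of mock SD, mock HFD, infected SD and infected HFD.

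Infection on the standard diet was compared first in fibroblasts. Those of infected SD held far more RNA of acute phase and antimicrobial genes than those of mock SD. Saa3, a serum amyloid A protein made in inflammation, was at 6593 CPM [6537, 6649] against 1.64 [0.897, 2.75], 4020-fold higher [2396, 7353]. Its gene (ENSMUSG00000040026) lies on chromosome 7 of GRCm38 at 46711998 to 46715700. Lcn2, which binds bacterial siderophores, was at 362 CPM against 0.351, and Slpi, an antimicrobial protease inhibitor, at 586 against 3.28. Of 12 measured members of the antimicrobial list, 8 were at least 2-fold higher and 1 lower, with a median log2 ratio of 6.29 [5.63, 7.29]. Lcn2 and Slpi were among 6 members under 20% of their level in another class. Without these 6 the median was 7.84, and with genes at 0 counts set to the floor it was 5.99. Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), the cathelicidin antimicrobial peptide, had 6 UMIs in fibroblasts of infected SD, 1 in infected HFD and 0 in both mock libraries, under the 30 UMIs that the size rule needs. With a captured UMI in 0 of 683 and 0 of 377 mock fibroblasts, the upper limits of these shares are 0.539% and 0.974%. Dermal papilla or sheath cells held 9 Camp UMIs in mock SD and 29 in infected SD.

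An Saa3 UMI was found in 39.8% [35.6, 44.2] of fibroblasts of infected SD and 74.3% [67.4, 80.5] of infected HFD, against 1.46% in mock SD and 3.98% in mock HFD. With each cell thinned to 1000 UMIs the shares were 26.1% [22.3, 30.1] and 57.5% [49.9, 64.8] against 0.301% and 0.813%, and 19, 8, 7 and 2 fibroblasts of mock SD, mock HFD, infected SD and infected HFD were left out. In T and NK cells, used as a background class for Saa3, the unthinned shares were 2.36%, 0.862%, 7.27% and 7.34%. Median depths were 11293, 18515, 15391 and 24960 UMIs in fibroblasts and 4201, 6233, 3800 and 5439 in T and NK cells.

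Genes of fat cell differentiation were lower in fibroblasts of infected SD. Of 20 measured members of the adipogenesis list, 9 were at least 2-fold lower and 0 higher, with a median of -0.80 [-1.003, -0.66]. Within cluster 1 the median was -0.23 with 2 members higher and 3 lower, and cluster 3, the highest in progenitor markers, held 271 cells in mock SD and 13 in infected SD. Gpx3, a secreted glutathione peroxidase, was 6.32-fold lower [5.97, 6.70], and Lpl, the lipoprotein lipase, 2.85-fold lower [2.59, 3.13]. The methyltransferase gene Inmt was 37.6-fold lower [24.7, 60.4], though higher in cluster 14 alone (log2 4.22), and Myoc, which encodes myocilin, 21.6-fold lower [18.9, 24.8]. Higher genes included Timp1, an inhibitor of matrix proteases, at 6.99-fold [6.56, 7.46], and the serine protease inhibitor Serpina3n at 5.25-fold [5.05, 5.45]. Cxcl5, a neutrophil-attracting chemokine, was 27.5-fold higher [19.98, 38.9], with 61.1% of its UMIs in 1 of 22 cells. Of 26 chemokines and cytokines, 14 were at least 2-fold higher and 1 lower, with a median of 1.18 [1.01, 1.56] or 0.38 without 11 members under 20% of their level in another class. The median was 0.86 within cluster 1 and 0.47 within cluster 14. Cxcl1, which also attracts neutrophils, was 3.20-fold lower [3.06, 3.35]. MHC class I presentation was higher, with a median of 0.73 [0.69, 0.81] over 13 members and the immunoproteasome gene Psmb8 2.29-fold higher [2.10, 2.49]. The interferon response list had a median of 0.34 [0.21, 0.51], with 4 of 22 members at least 2-fold higher; all 4 were among 11 members under 20% of another class, without which the median was 0.13. In all, 181 genes passed the size rule, 75 higher and 106 lower. Clusters 3, 1 and 14 held 271, 200 and 44 of 683 fibroblasts in mock SD, whereas clusters 1 and 14 held 275 and 85 of 517 in infected SD. Within cluster 14 alone the interferon median was -0.34, and within cluster 1 alone Myoc was higher (log2 2.43).

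Metallothionein and acute phase genes were higher in fibroblasts of infected SD, with a median of 1.94 [1.87, 2.04], or 1.28 over 6 members without those under 20% of another class. Medians of other lists were -0.43 for TGF-beta response and matrix, -0.33 for NF-kB and pattern recognition, -0.09 for complement and 0.06 for hypoxia and glycolysis. Complement was positive within cluster 1, at 0.94, and within cluster 14, at 0.70. Matrix proteases and inhibitors had a median of 0.03, lipid handling and fatty acid oxidation 0.11, dissociation stress and immediate early -0.26, and proliferation 0.23. Keratinocyte wound response had 5.10 over 4 members, all under 20% of another class. The inflammatory macrophage list had 0.87, neutrophil granule 0.99 and neutrophil activation 0.46, which turned to -1.34, -0.63 and -0.47 without members so limited, and resident macrophage had 0.28. Neutrophil activation was also negative under 5 alternatives, for example -0.13 with at least 500 genes.

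Infection on the high fat diet came with high acute phase and chemokine levels in fibroblasts. Saa3 was at 12385 CPM [12286, 12485] in infected HFD against 60.3 [54.6, 66.3] in mock HFD, 206-fold higher [187, 227], and 57.6% of the mock HFD UMIs came from 1 cell. Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624) was at 1118 CPM against 0 UMIs, at least 2597-fold higher. Csf3, the granulocyte growth factor G-CSF, was 419-fold higher [74.6, 16605] with 1 UMI in mock HFD. Il33, an alarmin, was 12.2-fold higher [10.7, 13.9] and Tnc, the matrix protein tenascin C, 25.8-fold higher [21.8, 30.8]. Of 26 chemokines and cytokines 16 were at least 2-fold higher and 0 lower, with a median of 1.86 [1.71, 2.07], which was 0.65 without 8 members under 20% of another class. The antimicrobial median was 4.96 [4.43, 5.68] with 8 of 12 at least 2-fold higher, and reached 7.55 when called doublets were kept. Adipogenesis had a median of -0.24 [-0.52, -0.09], with 3 of 18 members at least 2-fold lower and 2 higher, and -0.65 without 9 members under 20% of another class. Interferon response genes were lower, with a median of -0.48 [-0.64, -0.31] and 5 of 21 at least 2-fold lower, such as the transcription factor gene Irf1 at 2.96-fold [2.66, 3.29]. MHC class I presentation had -0.24 [-0.34, -0.15]. Without members under 20% of another class, 13 of 21 and 3 of 13, the interferon and MHC class I medians were -0.61 and -0.32. Within cluster 1 these 2 lists had -0.042 and 0.14. Of the lists of other cell types in the same fibroblasts, 4 were higher, with 5.29 for inflammatory macrophage (16 of 19 members under 20% of another class), 3.47 for neutrophil granule, 1.87 for neutrophil activation and 10.64 for keratinocyte wound response, and resident macrophage had -0.25 [-0.43, -0.19]. Without members so limited inflammatory macrophage had 0.079 and neutrophil activation -0.33, and all 3 keratinocyte members were limited.

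Glycolytic and dividing-cell genes were also higher in fibroblasts of infected HFD than of mock HFD. Hypoxia and glycolysis had 0.61 [0.50, 0.68], but 0.29 in cluster 1 alone, at percentile 88.4 among random lists. Proliferation had 0.76 [0.68, 1.01] with 7 of 16 members at least 2-fold higher, which was -0.04 in cluster 1 alone. In this comparison 198 genes passed the size rule, 94 higher and 104 lower. The neuropeptide gene Gal, the monooxygenase gene Fmo2, Inmt and Myoc were among the lower ones, Myoc at 12.8-fold [10.98, 15.02]. Of genes past the rule in both diets, 28 were higher in both (1.51 expected if independent) and 43 lower in both (3.64 expected), from separate libraries. Clusters 3 and 1 held 125 and 124 of 377 fibroblasts of mock HFD, and clusters 14 and 1 held 85 and 58 of 183 of infected HFD. Cluster 14, whose leading genes include Cxcl5, Saa3 and Il33, held 4 fibroblasts of mock HFD.

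**Figure D2:**
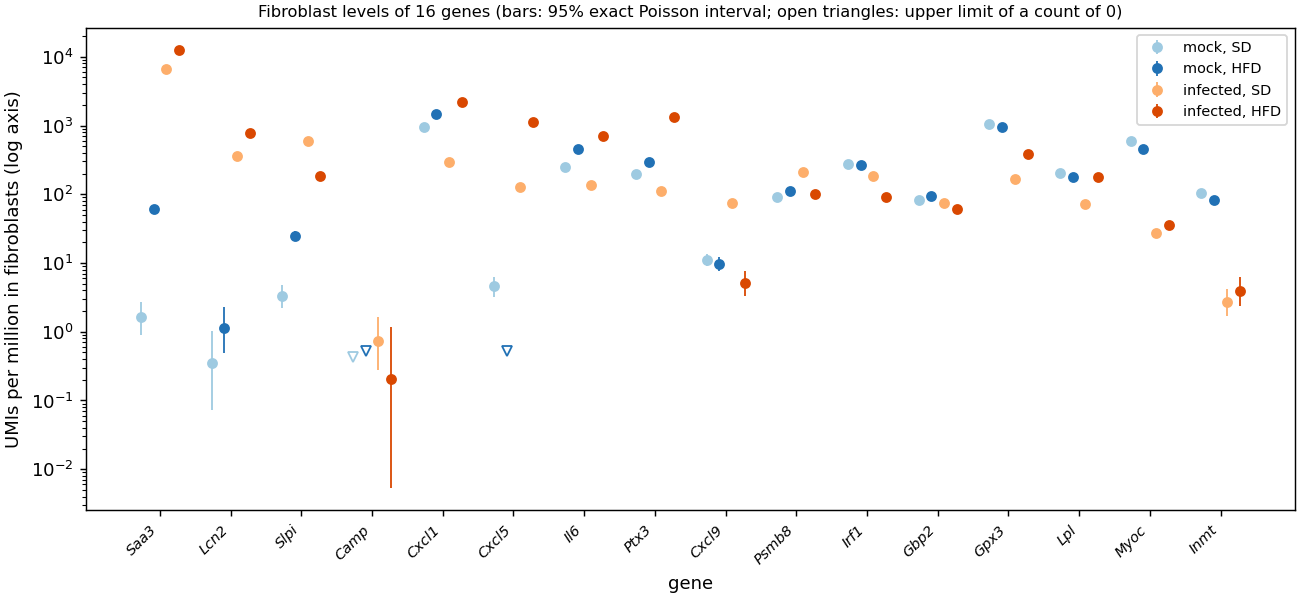
Levels of 16 genes in fibroblasts of the 4 libraries on a log axis, in CPM with exact Poisson 95% intervals. Saa3 was at 1.64 in mock SD, 60.3 in mock HFD, 6593 in infected SD and 12385 in infected HFD, and open triangles mark the upper limit of a count of 0.

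Diet without infection separated the fibroblasts by few genes. The metallothioneins Mt2 and Mt1, metal-binding proteins, were 2.23-fold [2.17, 2.30] and 2.001-fold [1.964, 2.04] higher in mock HFD than in mock SD. Prg4, which encodes the lubricant proteoglycan lubricin, was 5.002-fold higher [4.46, 5.63], and Ptgs2, the cyclooxygenase of inflammation, 2.02-fold higher [1.90, 2.14]. The matrix genes Tnc, Postn (periostin) and Cthrc1 were lower in mock HFD, by 6.86-fold [5.77, 8.21], 3.83-fold [3.57, 4.10] and 2.66-fold [2.42, 2.92]. Cluster 14, with Cthrc1 among its leading genes, held 44 of 683 fibroblasts in mock SD and 4 of 377 in mock HFD. Cluster 23, with Top2a among its leading genes, held 25 and 4. Of 26 members of TGF-beta response and matrix, 4 were at least 2-fold lower and 0 higher, with a median of -0.27 [-0.34, -0.21]. Chemokines and cytokines had a median of 0.53 [0.42, 0.60] over 22 members, with Il6, a cytokine of the acute phase response, 1.85-fold higher [1.75, 1.95]. Adipogenesis had -0.21 [-0.43, -0.13], with 6 of 19 members at least 2-fold lower, 5 of them under 20% of another class, and -0.027 without such members. Antimicrobial genes had a median of 0.26, interferon response 0.19 and MHC class I presentation 0.27. Saa3 was 36.8-fold higher [21.7, 67.8], with 57.6% of its UMIs in 1 of 15 cells. The size rule was passed by 23 genes, 16 higher and 7 lower, by 12 at Leiden resolution 0.5 and by 93 with each library clustered alone. In that clustering adipogenesis was at 0.57 and Tnc and Postn were higher, at 1.29 and 1.38, Tnc was also higher in cluster 1 alone (2.51), and proliferation, at -0.84 [-1.18, -0.72], was 0.45 in cluster 1 alone.

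Diet under infection separated them by more genes. Neutrophil-attracting chemokines were higher in fibroblasts of infected HFD than of infected SD, with Cxcl1 at 2225 against 293 CPM, 7.60-fold [7.27, 7.95], and Cxcl5 at 8.90-fold [8.32, 9.52]. Il6 was 5.15-fold higher [4.81, 5.52], and Ptx3, a secreted pattern recognition protein, 11.996-fold higher [11.2, 12.9], but lower in cluster 1 alone (log2 -2.31). Of 26 chemokines and cytokines, 17 were at least 2-fold higher and 2 lower, with a median of 1.88 [1.80, 1.97], and 1.71 without 9 members under 20% of another class. Lists of other cell types had 2.66 for inflammatory macrophage (17 of 19 members under 20% of another class), 2.26 for neutrophil activation (0.47 without 13 of 16 members so limited), 1.11 for neutrophil granule, 0.95 for keratinocyte wound response and -0.50 for resident macrophage. In cluster 14 alone the first 2 were 3.43 and 3.03, and in cluster 1 alone 0.70 and 0.23. Cxcl9, a chemokine induced by interferon gamma, was 14.3-fold lower [9.61, 22.3], with 41.7% of its infected SD UMIs in 1 cell. MHC class I presentation had a median of -0.86 [-0.93, -0.75], with 5 of 13 members at least 2-fold lower and 0 higher, among them the heavy chain H2-K1 at 2.12-fold [2.04, 2.21]. Its median was -0.36 in cluster 1 and -0.61 in cluster 14, and -0.75 without 2 members under 20% of another class. Interferon response had -0.65 [-0.81, -0.51], with 6 of 22 at least 2-fold lower, including the GTPase gene Iigp1 at 2.32-fold [2.01, 2.68] and Irf1 at 2.02-fold [1.81, 2.25]. That list was at -0.82 in cluster 1 and -0.25 in cluster 14. Of its 22 members 13 were under 20% of another class, among them 3 of the 6 at least 2-fold lower. Without these 13 members the interferon median was -0.65. Complement had 0.57 [0.48, 0.65], with its central component C3 2.99-fold higher [2.86, 3.12], but the list had 0.23 in cluster 1 and -0.20 in cluster 14. Hypoxia and glycolysis had 0.47 [0.37, 0.57], with Adm, the vasodilator adrenomedullin, 4.43-fold higher [3.87, 5.07], and the list at 0.046 in cluster 1 and 0.75 in cluster 14.

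Antimicrobial genes split in fibroblasts of the 2 infected libraries, with a median of -0.12, or -0.43 without members under 20% of another class, 0.21 in cluster 1 and -0.50 in cluster 14. Saa3 was 1.88-fold higher [1.86, 1.90] in infected HFD, whereas Slpi was 3.17-fold lower [2.95, 3.40]. Slpi in fibroblasts of infected SD was under 20% of its level in another class, so free RNA can supply it. Reg3g, a lectin that kills Gram-positive bacteria, was 50.8-fold lower [13.9, 423] with 2 UMIs in infected HFD. It is named as a list member, and whether 1 cell gave most of its UMIs was not checked. Metallothionein and acute phase genes had a median of 0.85 [0.78, 0.91], but 0.42 in cluster 1 and -0.38 in cluster 14. Adipogenesis had 0.11, with Gpx3 and Lpl 2.31-fold and 2.51-fold higher. All 4 members at least 2-fold lower were under 20% of another class, and without such members the median was 0.78. Over all measured members it was 0.18 in cluster 1 and 0.23 in cluster 14, at percentiles 95.2 and 83.6 among random lists. There were 185 genes past the size rule, 135 higher and 50 lower, 302 with called doublets kept and 41 in cluster 1 alone. The chemokine median was 0.10 in cluster 1 alone and 1.28 in cluster 14 alone, and cluster 14 held 85 of 517 fibroblasts in infected SD and 85 of 183 in infected HFD.

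**Figure D3:**
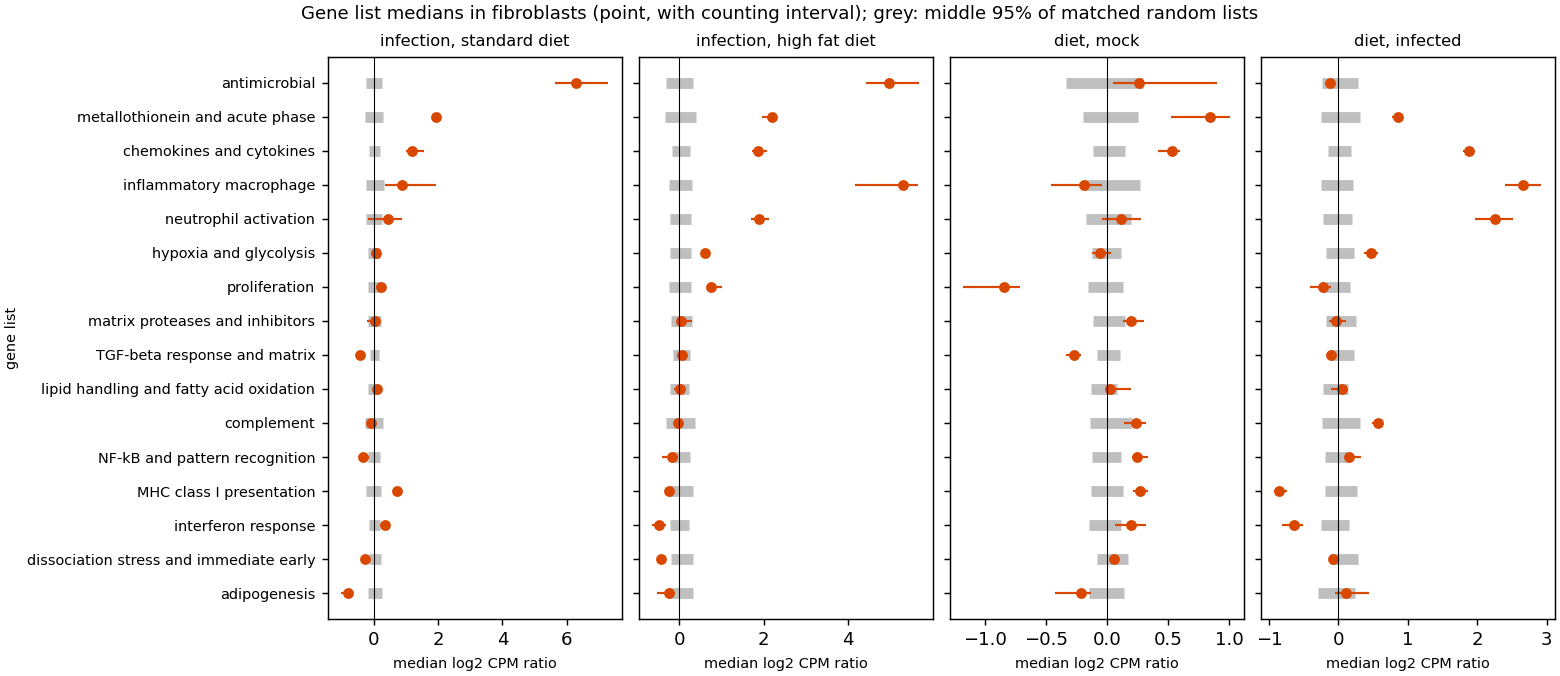
Medians of 16 gene lists in fibroblasts for the 4 comparisons, with counting intervals over the middle 95% of matched random lists in grey. MHC class I presentation was at 0.73 and -0.24 for infection on SD and HFD, and at 0.27 and -0.86 for diet in mock and infected skin.

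The diet by infection difference, HFD minus SD, was negative for MHC class I presentation and interferon response in fibroblasts. MHC class I presentation had -1.02 [-1.31, -0.95] with 13 of 13 members negative, and interferon response -0.71 [-0.97, -0.52] with 18 of 21 negative. The difference was positive for chemokines and cytokines, at 1.60 [1.23, 1.71] with 20 of 26 members positive, and -0.44 in cluster 1 alone. Cluster 14 held 6.44% and 16.4% of fibroblasts in mock SD and infected SD, and 1.06% and 46.4% in mock HFD and infected HFD. Of the lists of other cell types, 4 were positive too, at 2.76 for inflammatory macrophage, 2.11 for neutrophil activation, 1.35 for neutrophil granule and 4.97 for keratinocyte wound response, and resident macrophage had -0.37. Hypoxia and glycolysis had 0.58 [0.47, 0.69] with 16 of 16 positive, and proliferation 0.62 [0.50, 0.82]. This did not hold within cluster 1, where the infection medians on SD and HFD were 0.37 and 0.29 for hypoxia and glycolysis and 0.96 and -0.043 for proliferation. Adipogenesis had 0.44 [0.27, 0.78] with 14 of 19 positive, and -0.48 with each library clustered alone. Antimicrobial genes had -0.45 [-0.79, -0.28] with 8 of 12 negative, and 0.34 with at least 500 genes per cell. In macrophages the difference was 0.86 [0.72, 1.10] for chemokines and cytokines, 0.66 [0.57, 0.93] for NF-kB and pattern recognition and 0.51 [0.37, 0.74] for the inflammatory macrophage list. Interferon response had -0.59 [-0.98, -0.39] there, against a median of -0.23 and a middle 95% from -0.56 to 0.13 for matched random lists.

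Macrophages and monocytes of both infected libraries held RNA of inducible effector genes that was absent or rare in mock skin. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, had 0 UMIs in both mock libraries and was at least 50.7-fold higher in infected SD and at least 118-fold in infected HFD. Arg1, an arginase that competes for the same substrate, was 242-fold higher [82.7, 1174] in infected HFD over 3 UMIs in mock HFD. Inhba, a subunit of activin A, was 52.3-fold [22.2, 162] and 15.8-fold [10.9, 23.9] higher on SD and HFD. The inflammatory macrophage list had a median of 0.89 [0.81, 1.06] with 9 of 20 members at least 2-fold higher on SD, and 1.30 [1.24, 1.43] with 15 of 20 on HFD. Within cluster 7 it went opposite ways. There it was -0.92 on SD, with 1 member at least 2-fold higher and 9 lower, and 0.90 on HFD, with 9 higher and 0 lower. The glycolytic enzyme gene Pgk1 was 3.56-fold [2.86, 4.45] and 3.93-fold [3.31, 4.71] higher, and hypoxia and glycolysis had 0.94 [0.85, 1.22] and 0.85 [0.73, 0.97], against 0.47 and 0.06 within cluster 7.

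Genes of resident macrophages were lower in both infected libraries. The list had -1.14 [-1.32, -0.92] on SD and -1.17 [-1.23, -1.01] on HFD, with 9 and 8 of 15 members at least 2-fold lower, and -0.67 and -0.57 within cluster 7, with 5 and 2 lower. On HFD the lectin gene Cd209f was 9.86-fold lower [6.29, 16.2], the folate receptor gene Folr2 3.78-fold [3.19, 4.49] and the hyaluronan receptor gene Lyve1 9.27-fold [6.01, 14.7]. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted marker of alternative activation, was at 561 CPM in mock SD, in 18 of 189 cells, and had 0 UMIs in infected SD, at least 285-fold lower. It also had 0 UMIs in the 60 cells of mock HFD and 4 in infected HFD, so it was seen almost only in mock SD. Interferon response had -0.15 [-0.25, 0.02] on SD and -0.75 [-0.95, -0.58] on HFD, where 10 of 22 members were at least 2-fold lower and Ifit3, an antiviral protein, was 15.1-fold lower [8.93, 27.1]. Within cluster 7 the interferon medians were 0.0073 on SD and -1.34 on HFD. TGF-beta response and matrix had -1.76 on SD and 0.37 on HFD, or 0.06 and 0.61 without members under 20% of another class and -1.42 and 0.44 within cluster 7. Over the 17 members measured in the 4 libraries together the medians were -0.83 and 0.0087. The size rule was passed by 212 genes on SD, 94 higher and 118 lower, and by 312 on HFD, 165 higher and 147 lower. With the median of all genes at -0.16 on HFD, centring gave 216 higher and 86 lower, and TMM scaling 245 and 61. Both diets shared 25 higher genes (3.22 expected) and 38 lower ones (4.21 expected). Cluster 7 held 177 of 189 macrophages in mock SD, 47 of 60 in mock HFD, 126 of 218 in infected SD and 104 of 252 in infected HFD. Cluster 19 held 12, 13, 58 and 35 in the same order, and cluster 33 held 34 and 113 in the infected libraries only.

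Macrophages of mock HFD held more interferon RNA than those of mock SD. The list had 0.70 [0.55, 0.90] with 9 of 22 members at least 2-fold higher and 0 lower, including Ifit3 at 4.78-fold [3.11, 7.53] and Oasl2, an antiviral protein of the OAS family, at 2.99-fold [2.13, 4.25]. Apoe, a lipid carrier, was 3.07-fold lower [2.97, 3.16] and Cd74, the MHC class II invariant chain, 2.42-fold lower [2.34, 2.497]. S100a9 and Spp1 were higher with 99.0% and 95.2% of UMIs in 1 cell. There were 107 genes past the size rule, 78 higher and 29 lower, at a median of 0.12 over all genes; centring gave 42 and 39, and TMM scaling 41 and 48.

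Macrophages of infected HFD held more chemokine and inflammatory RNA than those of infected SD. The neutrophil chemokine gene Cxcl3 was 8.75-fold higher [7.68, 10.0], the prostaglandin E synthase gene Ptges 6.22-fold [5.32, 7.31], Csf3 7.37-fold [5.25, 10.6], Arg1 3.95-fold [3.54, 4.41] and Nos2 3.59-fold [3.09, 4.19]. Medians were 1.31 [1.205, 1.36] for the inflammatory macrophage list, with 13 of 20 members at least 2-fold higher, and 0.94 [0.89, 1.24] for chemokines and cytokines. Hypoxia and glycolysis had 0.81 [0.73, 0.96]. Within cluster 7 these medians were 1.48, 1.48 and 0.25 in that order. Cd72, a receptor of the lectin family, was 5.72-fold lower [4.39, 7.55]. Past the size rule were 154 genes, 119 higher and 35 lower, or 184 and 97 with the mean of each cell's CPM. With each library clustered alone, Cxcl3 was at -0.03, Ptges at -3.57 and hypoxia and glycolysis at -0.23. That clustering kept the name of 215 of 218 macrophages of infected SD and 140 of 252 of infected HFD. Cluster 33, with Arg1, Nos2 and Ptges among its 10 leading genes, held 44.8% of the class in infected HFD. It was named on 4 detected markers, with 0 of them among its leading genes.

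T and NK cells of infected HFD held more RNA of Il17a, a cytokine that drives neutrophil recruitment, than those of infected SD. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was at 2350 CPM [2248, 2456] against 308 [278, 341], 7.63-fold higher [6.83, 8.54], with 73.8% of the infected HFD UMIs in 6 of 109 cells, and at 427 and 1220 CPM in mock SD and mock HFD. A UMI was found in 33.9% [25.1, 43.6] of cells of infected HFD, 14.5% [10.7, 19.1] of infected SD, 30.2% of mock HFD and 14.96% of mock SD. Thinned shares were 23.1%, 10.2%, 19.1% and 11.3% in that order, with 1, 6, 1 and 3 cells left out. Fibroblasts had an Il17a UMI in 2.73%, 0.193%, 0.531% and 0% of cells. Il17f, a related cytokine gene, was 3.82-fold higher [3.11, 4.73] with 51.4% of its UMIs in 1 cell. Granzyme C (Gzmc) was 15.7-fold lower [13.6, 18.2], the cathepsin gene Ctsw 3.70-fold and the lymphocyte receptor gene Cd7 4.15-fold, but within cluster 12 Gzmc was higher (log2 5.21). Past the size rule were 135 genes, 60 higher and 75 lower.

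In mock skin, 3 genes expressed by gamma delta T cells were among those that differed by diet in T and NK cells. Trdc, the constant region of the delta chain, was 3.21-fold higher [2.90, 3.57] in mock HFD, the scavenger receptor gene Cd163l1 3.86-fold [3.08, 4.89] and the variable segment Trdv4 3.76-fold [2.55, 5.73]. Gzmc was 11.3-fold lower [8.84, 14.5] and Xcl1, a chemokine of NK and CD8 T cells, 3.32-fold lower. Diet gave 57 genes past the rule here, 39 higher and 18 lower, and the 2 diet comparisons shared 9 higher genes (0.384 expected) and 4 lower ones (0.268 expected). Clusters 4 and 12 held 61 and 43 T and NK cells in mock SD, 35 and 62 in mock HFD, 88 and 94 in infected SD and 43 and 40 in infected HFD. Cluster 17, with Gzmc, Xcl1 and Ctsw among its leading genes, held 16, 9, 43 and 13 in that order of libraries. Cluster 22, with Cd7 among its leading genes, held 7, 10, 64 and 13.

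T and NK cells were also compared by infection on each diet. On SD the heat shock gene Hspa1a was 3.27-fold higher [3.07, 3.49], and the costimulatory receptor genes Icos and Cd27 were 2.18-fold and 2.32-fold lower. On HFD Il22, a cytokine acting on epithelium, was 67.7-fold higher [18.4, 564] over 2 UMIs, with 58.3% of its UMIs in 1 cell, and the replication factor gene Pclaf was 7.36-fold higher. The neuropeptide gene Calca was 7.78-fold lower. The size rule was passed by 31 genes on SD, 19 higher and 12 lower, and by 168 on HFD, 88 higher and 80 lower. With the mean of each cell's CPM these were 67 on SD and 101 on HFD, the latter 42 higher and 59 lower.

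Neutrophils were compared between the infected libraries only. Gdf15, a stress-induced cytokine, was 11.8-fold higher [5.68, 29.5] in infected HFD, and Il23a, an IL-23 subunit that sustains IL-17 producing cells, 2.86-fold higher [2.29, 3.61]. Haptoglobin (Hp) was 2.37-fold lower [2.07, 2.71], annexin A1 (Anxa1), which restrains neutrophil entry, 2.55-fold lower [2.04, 3.16] and the collagenase gene Mmp8 3.06-fold lower [1.90, 4.86]. Medians were 0.45 [0.26, 0.65] for chemokines and cytokines, 0.30 [0.19, 0.41] for interferon response and 0.32 [0.27, 0.46] for NF-kB and pattern recognition. Within clusters 27, 29 and 32 the interferon median was 0.02, -0.01 and 0.17, while cluster 28, whose leading genes include the interferon-induced Rsad2 and Gbp5, held 18 of 309 and 274 of 1091 neutrophils. Neutrophil activation had 0.30 [0.27, 0.39] and neutrophil granule -0.50 [-0.79, -0.12], the latter at -0.34, 0.19 and -0.67 within clusters 27, 29 and 32. Hypoxia and glycolysis had -0.16, and 0.10 with TMM scaling. Neutrophils had 20 genes past the size rule, 8 higher and 12 lower, or 10 and 6 after centring and 22 and 4 with TMM scaling. Clusters 27, 32 and 29 held 109, 95 and 87 of 309 neutrophils in infected SD, and clusters 27, 28 and 29 held 317, 274 and 255 of 1091 in infected HFD.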

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

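Of the 14 tests reported here, 12 were chosen after the result they bear on had been seen, and those of neutrophil RNA and of the 5% of cells with most Il17a UMIs were set out earlier. All differences between the diets given here were untested, since each group was 1 library.

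Interferon response in fibroblasts had an infection median of 0.34 on SD and -0.48 on HFD with a median difference of -0.71, and MHC class I presentation 0.73 and -0.24. Within cluster 1 the interferon medians were 1.07 and -0.042 and those of MHC class I 0.99 and 0.14, so the directions were not opposite there for MHC class I and interferon was near 0 on HFD, and cluster 14 gave -0.34 for interferon on SD. The differences within cluster 1 were -0.94 [-1.23, -0.65] and -0.71 [-0.91, -0.67], which argues against a different mix of fibroblast clusters as the whole cause of the differences, and TMM scaling gave -0.71. A first test of RNA from other cells left 2 interferon members (median -0.16) and 1 MHC class I member (-0.97) and decided nothing. The profiles of the other classes with at least 20 cells in a library, dermal papilla or sheath apart, were then taken away. More classes reached 20 cells in the SD libraries than in the HFD ones. The differences were then -0.89 [-1.12, -0.68] and -1.05 [-1.35, -0.98], but the inflammatory macrophage list in fibroblasts was not lowered. RNA from other cells therefore stays open, as do animal and library differences.

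Chemokines and cytokines were higher in fibroblasts of infected HFD than of infected SD, with a median of 1.88. Cluster 14 supplied 27.1% of the UMIs of clusters 1 and 14 in infected SD and 69.9% in infected HFD. With both libraries held at the shares of infected SD the median over clusters 1 and 14 was 1.13 [0.997, 1.17]. The value of 1.88 covers the other fibroblast clusters too, so the part that the mix accounts for cannot be read from the 2 values. The clusters were themselves made with such genes. Taking away the neutrophil profile, 0.139% and 0.478% of fibroblast UMIs in the 2 libraries, left 1.88 [1.74, 1.963], with neutrophil activation at 2.26 before and 2.35 after. Taking away the other classes with at least 20 cells in a library, dermal papilla or sheath apart, left 1.85 [1.79, 1.93]. Pericytes and smooth muscle were taken away at 1.60% in infected SD but were too few in infected HFD. Inflammatory macrophage was at 2.66 before and 3.79 after. Neither test thus reached the lists of other cells, and their RNA stays open beside animal and library differences.

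Il17a was 7.63-fold higher in T and NK cells of infected HFD than of infected SD. Within cluster 12, which held 32.5% and 36.7% of these cells, it was 5.61-fold higher [4.99, 6.32], so the share of that cluster does not supply the whole fold. Il17a itself led the genes of cluster 12, and these limits count UMIs rather than cells, so the mix of cells within it stays open. The ratio of the thinned shares of cells with a UMI was 2.26, so deeper cells do not supply the whole difference in those shares. The 5% of cells with most Il17a UMIs held 78.1% and 73.8% of them, but were 15 of 42 cells with a UMI in infected SD and 6 of 37 in infected HFD, so the 9.76-fold [7.73, 12.5] that remained without them decides nothing. Without the 20% of cells with a UMI that held most, 9 and 8 cells, it was 4.596-fold higher, with limits of 1.62 and 11.6 over resampled cells, so a few cells with very many UMIs stay open as a cause. Mock HFD was also above mock SD, at 1220 against 427 CPM.

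Other infection ratios had opposite signs on the 2 diets. In macrophages, TGF-beta response and matrix had -1.76 on SD and 0.37 on HFD, each over the members measured for that diet. The median difference was 1.01 over 17 members measured in the 4 libraries together. Their medians were -0.83 on SD and 0.0087 on HFD, so near 0 on HFD. Without members under 20% of another class the medians of both diets were positive, at 0.06 and 0.61. With each library clustered alone SD was 0.28, and within cluster 7 the signs stayed opposite, at -1.42 and 0.44. Cd7 in T and NK cells had 1.09 on SD and -1.33 on HFD, a difference of -2.43. It was among the leading genes of cluster 22. That cluster held 5.51% and 22.1% of these cells in mock SD and infected SD, and 8.62% and 11.9% in mock HFD and infected HFD. The share was thus higher with infection on both diets. In fibroblasts, Gldn, which encodes gliomedin, had 1.63 and -1.17, a difference of -2.80. Plac8 there had -1.11 and 1.60, a difference of 2.71, and the sulfatase gene Sulf1 -1.08 and 1.07, a difference of 2.15. In macrophages, the cyclin gene Ccnd3 had 1.499 and -1.28, a difference of -2.78. The receptor gene Cd72 had 1.13 and -2.23, a difference of -3.36, and Gpnmb, a membrane glycoprotein gene, 1.58 and -1.70, a difference of -3.28. Ms4a4c, among the leading genes of cluster 19, had 1.06 and -1.05, a difference of -2.11. That cluster held 6.35% of macrophages in mock SD and 26.6% in infected SD, but 21.7% in mock HFD and 13.9% in infected HFD. The survival gene Bcl2a1b had -1.85 and 0.999, a difference of 2.85, and Hmox1, the haem oxygenase gene, -1.03 and 1.29, a difference of 2.32.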

How the results depend on the processing

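Alternatives chosen after the results were seen were the cells with the highest doublet scores left out, fibroblasts without clusters 23 and 25, with dermal papilla or sheath cells added, or from cluster 1 or cluster 14 alone, macrophages from cluster 7 alone, and T and NK cells from cluster 12 alone. No paired analysis was possible because each group was 1 library, and no replicate could be left out. Thinning applied to shares of classes and of cells with a UMI only, and moved 2 of 44 shares of classes, both of fibroblasts in infected HFD. The cause of the shifts was not tested, beyond what an alternative brings by construction. Of 2202 list medians, 1676 stayed the same, 492 moved and 34 reversed. Of 3076 values of named genes, 2478 stayed, 567 moved and 31 reversed. Of 294 counts of genes, 245 were within 1.5 times and 49 were not. Of 130 diet by infection medians, 91 stayed, 33 moved and 6 reversed, and of 396 shares of classes, 302 stayed and 94 moved. Centring moved 23 list medians, 4 diet by infection medians and 3 named genes, and at most 10% mitochondrial UMIs moved 7 named genes and 2 shares. Neither reversed a value, and at least 10 UMIs moved none of 17 counts. Comparisons are written as SD or HFD infection and mock or infected diet.

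In fibroblasts, the counts were 181 for SD infection, 198 for HFD infection, 23 for mock diet and 185 for infected diet. A ratio of at least 3 gave 72, 78, 8 and 71, which is fewer by construction. The mock diet count was 12 at Leiden resolution 0.5, 93 with each library clustered alone and 15 with the mean of each cell's CPM. The infected diet count was 302 with called doublets kept and 41 in cluster 1 alone.

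The antimicrobial median of fibroblasts, 6.29 for SD infection, was 4.74 with dermal papilla or sheath cells counted as fibroblasts, 5.10 in cluster 1 alone, 5.16 without clusters 23 and 25, 4.77 without the highest doublet scores and 5.22 with no cell filter. For HFD infection it was 4.96, and 7.54 at Leiden resolution 2, 6.39 with at least 500 genes, 7.55 with called doublets kept, 4.43 in cluster 1 alone and 7.51 without the highest doublet scores. Its diet by infection difference, -0.45, was 0.34 with at least 500 genes, 0.32 with called doublets kept, 0.19 with dermal papilla or sheath cells and 0.0291 without the highest doublet scores.

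The chemokine median of fibroblasts for infected diet, 1.88, was 2.03 at Leiden resolution 2, 2.45 with at least 500 genes, 1.69 with called doublets kept and 2.35 with dermal papilla or sheath cells. It was 0.10 in cluster 1 alone, 1.28 in cluster 14 alone, 2.07 without clusters 23 and 25, 2.37 without the highest doublet scores, 1.80 with the mean of each cell's CPM and 2.25 with no cell filter. The diet by infection difference of chemokines, 1.60, was -0.44 in cluster 1 alone.

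Interferon response of fibroblasts had 0.34 for SD infection, and 0.57 with at least 500 genes, 1.30 with each library clustered alone, 1.07 in cluster 1 alone and -0.34 in cluster 14 alone. For HFD infection it had -0.48, and -0.25 with dermal papilla or sheath cells and -0.042 in cluster 1 alone. Adipogenesis for mock diet, -0.21, was 0.57 with each library clustered alone, and its diet by infection difference, 0.44, was -0.48. That clustering gives other names to cells, and 280 of 683, 362 of 377, 299 of 517 and 177 of 183 fibroblasts kept theirs.

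Neutrophil activation in fibroblasts for SD infection, 0.46, was -0.13 with at least 500 genes, -0.12 with dermal papilla or sheath cells, -0.27 in cluster 14 alone, -0.11 without clusters 23 and 25 and -0.18 without the highest doublet scores, and for HFD infection it was -0.19 in cluster 1 alone. Proliferation was -0.10 for SD infection in cluster 14 alone and -0.0434 for HFD infection in cluster 1 alone. For mock diet, where it was -0.84, it was 0.40 with each library clustered alone, 0.45 in cluster 1 alone and 0.14 with no cell filter. Complement was -0.0947 for mock diet with the mean of each cell's CPM. In cluster 14 alone the inflammatory macrophage list was -0.23 and neutrophil granule -0.86 for SD infection, and complement was -0.20 and metallothionein and acute phase -0.38 for infected diet. Resident macrophage was 0.15 for infected diet in cluster 1 alone.

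Named genes of fibroblasts also reversed. With each library clustered alone, Thbs4 was at 3.35, Col8a1 at 4.96 and Fmo2 at 1.12 for SD infection, Tnc at 1.29 and Postn at 1.38 for mock diet, and Tnmd at 0.37 for infected diet. In cluster 1 alone, Myoc was at 2.43 for SD infection and Mgp at 8.25 for HFD infection. Sbsn was at -0.19 and Tnc at 2.51 for mock diet, and Dmkn at -2.58, Sbsn at -1.27, Ptx3 at -2.31 and Gldn at 0.34 for infected diet. In cluster 14 alone, Cxcl9 was at -1.91, Inmt at 4.22, Chrdl1 at 3.002 and Fmo2 at 0.61 for SD infection, and Gldn at 0.40 for infected diet. Top2a for mock diet was at 0.73 at Leiden resolution 0.5, 0.73 without clusters 23 and 25 and 0.46 with no cell filter.

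In macrophages, the counts were 212, 312, 107 and 154 in the same order of comparisons. Each library clustered alone gave 454, 141, 275 and 95, the mean of each cell's CPM 327, 597, 191 and 281, and a ratio of at least 3 gave 66, 132, 30 and 45. Clustered alone, 115 of 189, 59 of 60, 215 of 218 and 140 of 252 macrophages kept their name in mock SD, mock HFD, infected SD and infected HFD. Since the mean of each cell's CPM keeps the interval width of the sums, its counts are not like for like. The HFD infection count was 130 in cluster 7 alone, and the infected diet count 97 with a background limit of 50%. For SD infection, TGF-beta response and matrix was 0.28 with each library clustered alone, adipogenesis 0.00333 and proliferation 0.0428 with the mean of each cell's CPM, and the inflammatory macrophage list -0.92 and AA467197 -1.98 in cluster 7 alone. For HFD infection with each library clustered alone, antimicrobial was -0.45, matrix proteases and inhibitors -0.0673, keratinocyte wound response -0.34 and neutrophil granule -0.64, and TGF-beta response and matrix was -0.15 with the mean of each cell's CPM. For infected diet with each library clustered alone, hypoxia and glycolysis was -0.23, Cxcl3 -0.0339, Cd200 -2.89 and Ptges -3.57. TGF-beta response and matrix was 0.24 there with at least 500 genes, and matrix proteases and inhibitors -0.0476 in cluster 7 alone and -0.0306 with the mean of each cell's CPM.

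In T and NK cells, the counts were 31, 168, 57 and 135. A ratio of at least 3 gave 10, 69, 27 and 48. The SD infection count was 67 with the mean of each cell's CPM and 50 with no background filter. The HFD infection count was 253 in cluster 12 alone and 101 with the mean of each cell's CPM, where 42 were higher and 59 lower. The mock diet count was 32 with at least 100 UMIs, and the infected diet count 75 with the mean of each cell's CPM. Gzmc for infected diet was at 5.21 in cluster 12 alone, and Ccl1 for SD infection at -0.43 without the highest doublet scores.

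Neutrophils were 12.4% and 55.6% of infected SD and infected HFD with at least 500 genes, and 12.4% and 51.6% with no cell filter. Their count of 20 was 13 with a background limit of 50%, 35 with no background filter and 4 with a ratio of at least 3. With TMM scaling, hypoxia and glycolysis was 0.10 and dissociation stress and immediate early 0.0766.

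The count of 110 in dendritic and Langerhans cells was 290 with the mean of each cell's CPM and 45 with a ratio of at least 3. That of 112 in lymphatic endothelium was 233, with 84 higher and 149 lower, and 31. In dermal papilla or sheath cells the count of 44 for SD infection was 118 with each library clustered alone, 26 with a background limit of 50% and 10 with a ratio of at least 3. The count of 17 for mock diet was 28 with at least 500 genes, 10 with a background limit of 50%, 46 with the mean of each cell's CPM, 33 with no background filter, 29 with no cell filter and 5 with a ratio of at least 3. Mgp in these cells for SD infection was at -1.57 at Leiden resolution 2, -5.13 with at least 500 genes and -3.58 with no cell filter.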

Other observations

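Dendritic and Langerhans cells, which carry antigen to lymph nodes, were compared between infected SD and mock SD only, with 78 cells in each. Fabp5, a fatty acid binding protein, was 12.7-fold higher [10.2, 15.99] in infected SD. The growth factor gene Pgf was 9.64-fold higher [6.23, 15.6], and Il4i1, an amino acid oxidase that restrains T cells, 9.49-fold higher [5.39, 18.2]. Tnfrsf9, the costimulatory receptor 4-1BB, was at least 22.9-fold higher, in 9 cells with 40.0% of its UMIs in 1 of them. The tetraspanin gene Cd81 was 6.01-fold lower [4.24, 8.72] and the adhesion gene Cadm1 4.11-fold lower [2.53, 6.96]. Retnla was 26.9-fold lower, with 93.3% of its mock SD UMIs in 1 cell. The size rule was passed by 110 genes, 56 higher and 54 lower.

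Lymphatic endothelial cells, which line the vessels that drain skin, were also compared between infected SD and mock SD only. Lcn2 was 2.22-fold higher [2.004, 2.46] in infected SD, Serpina3n 3.30-fold higher [2.81, 3.87] and the aggrecan-cleaving protease gene Adamts5 4.72-fold higher. Irf1 was 4.16-fold lower [3.15, 5.59], the neurotensin gene Nts 3.02-fold lower [2.77, 3.30] and Igfbp5, a carrier of insulin-like growth factors, 3.47-fold lower [3.18, 3.79]. The size rule was passed by 112 genes, 17 higher and 95 lower, or 84 and 149 with the mean of each cell's CPM.

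Cells of the dermal papilla or sheath were compared by infection on SD and by diet in mock skin. Rspo3, which strengthens Wnt signals, was 3.01-fold higher [2.76, 3.28] in infected SD than in mock SD and Cd24a, a surface glycoprotein gene, 3.57-fold higher [3.18, 4.02]. Corin, a protease of the papilla, was 3.97-fold lower [2.87, 5.59], Irf1 2.69-fold lower [2.38, 3.04] and Zfp36, which destabilises cytokine RNA, 2.94-fold lower. Mgp, an inhibitor of calcification, was 6.53-fold higher with 93.0% of its UMIs in 1 cell, but lower with no cell filter (log2 -3.58), with at least 500 genes (-5.13) and at Leiden resolution 2 (-1.57). Past the rule were 44 genes, 21 higher and 23 lower, or 18 and 35 with the mean of each cell's CPM. In mock HFD over mock SD, Hmox1 was 2.81-fold higher [2.41, 3.27], Corin 5.77-fold lower [3.40, 10.5] and Crabp1, which binds retinoic acid, 2.25-fold lower, with 17 genes past the rule.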
